A study of Drosophila melanogaster with 16 samples.

How the data were processed

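Chromatin was immunoprecipitated from fly heads with antibodies against ROW, WOC, HP1c, HP1b and H3K4me3 or with IgG, and the bound DNA was sequenced, in 16 libraries (3 each for ROW, WOC, HP1c and H3K4me3, 2 each for HP1b and IgG). Groups and replicate numbers were taken from the sample labels. The submitters' processing notes name the build dm3 and the tools Bowtie2, SAMtools, MACS2 and deepTools; their versions, thresholds and roles are not given in the sources used here. The authors deposited 1 peak list for each of the 5 antibodies, so that replicates had been pooled or combined before deposit, by a route that is not given in the sources used here. Per the labels, each factor list belongs to all replicates of its antibody. The deposited ROW, WOC, HP1c and HP1b lists hold the chromosome, start and end of each peak in base pairs and no value per peak. The deposited H3K4me3 list adds the authors' fold enrichment over background at the summit (a ratio), the -log10 of the q-value and the summit position, and its peak names point to calling with MACS2 against IgG. In that list the -log10 q-value was at least 3.02. Fold enrichment and q-value served only to describe or rank peaks within that list. No read counts per library were used, so depth is unknown: a shallow library gives fewer and stronger peaks, and absence of a peak shows only that none was called.

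The chromosome names, including heterochromatin (Het), unplaced (U and Uextra) and mitochondrial contigs, are those of dm3. The gene table at hand belongs to a later genome release, so none of its coordinates were used. The analyses planned on gene promoters, gene lists, head-to-head genes and sequence motifs were therefore not run, and genes are not named. Coordinates are printed 1-based.

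Peaks of different lists were called shared when they overlapped by at least 1 bp. Chance overlap was estimated from 10000 circular shifts of the other list along each arm, which keep peak widths and clustering (1000 shifts for alternatives and for the count of regions with all 4 factors). The extent of an arm was taken from the outermost peaks of the 5 lists. One-sided permutation p-values were adjusted by Benjamini-Hochberg over the 12 ordered factor pairs and over the 4 comparisons with H3K4me3. Pairs of factors within H3K4me3 peaks (6 pairs) and arms (28 tests against H3K4me3 peaks) were tested with Fisher's exact test, two-sided, adjusted by the same method, with Woolf intervals for odds ratios. Overlapping factor peaks were merged into regions for the combinations. Width was related to the number of other factors by Spearman's rho with 100000 resamples. Distances to H3K4me3 summits were compared with 10000 resamples, with percentile bootstrap intervals from 1000 draws. Shares carry 95% Wilson intervals, which cover counting error only. An adjusted p under 0.05 was the threshold. The mitochondrial peaks were left out of distances because the H3K4me3 list has none there.

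Named regions followed a rule fixed before the data were examined: the 3 widest peaks of each factor, the 3 H3K4me3 peaks with the highest -log10 q, and for 6 classes of regions the 3 with the highest H3K4me3 value; examples from these are printed. The shift test was tried with the ROW peaks against simulated lists built from the WOC peaks. These were placed at random along each arm, without the clustering of the real list. Of 100 unrelated lists, 4 had an unadjusted p under 0.05 in the shift test. A list with 1468 planted peaks, from which overlapping peaks were then dropped, gave 1377 overlaps above the mean of its shifts. Alternatives covered the definition of overlap (0.5 of the shorter peak, centres within 200 bp, a gap of 500 bp), the peaks above the median of each list (by width, or for H3K4me3 by -log10 q or fold), uniform random placement, the main arms alone, H3K4me3 strata, merging over 200 bp, arm length as background (exact binomial test) and the H3K4me3 centre in place of its summit. Others were added after seeing the data: leaving out U and Uextra, centres within 200 bp for width and sharing, all H3K4me3 peaks as background for the combinations, factor peaks narrower than the median for distances, and the length of the main arms as background for proximal shares. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.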

Results

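Chromatin immunoprecipitation followed by sequencing was carried out on heads of Drosophila melanogaster of a control genotype (a driver stock crossed to a white-eyed wild-type background). The antibodies were against ROW, a zinc-finger chromatin protein, WOC, a zinc-finger protein known as its partner, and HP1c and HP1b, which are members of the heterochromatin protein 1 family. H3K4me3, the histone mark of active promoters, and non-specific IgG were profiled beside them. The 16 libraries comprised 3 each for ROW, WOC, HP1c and H3K4me3 and 2 each for HP1b and IgG. Peaks were analysed as 1 list per antibody, in which the replicates had been combined. The spread between replicates is therefore unknown, and so is the sequencing depth of each library. All p-values and intervals below describe the peaks of these 5 lists, which are not independent replicates, and cover no variation between flies. Tests of 1 factor list against another treat their peaks as separate, although many sites stand in both lists, so those p-values are approximate. All coordinates are dm3.

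ROW had 5302 peaks covering 2.87 Mb, WOC 4896 peaks covering 2.46 Mb, HP1c 4252 peaks covering 1.91 Mb and HP1b 2508 peaks covering 1.13 Mb. Median peak width was 449.5 bp for ROW, 423 bp for WOC, 373 bp for HP1c and 371 bp for HP1b. The H3K4me3 list held 6170 peaks of median width 606 bp, with a median fold enrichment of 3.57 in the authors' peak values. The number of peaks in a list depends on antibody and depth as well as on binding, so the lists are compared by position and not by length. The widest ROW and WOC peaks outside the mitochondrial genome lay on chromosome 4, at 1217066 to 1222679 for ROW (5614 bp) and at 1217078 to 1222674 for WOC (5597 bp). HP1c (1218711 to 1222611, 3901 bp) and HP1b (1218772 to 1222614, 3843 bp) had their widest non-mitochondrial peaks inside the same interval. The next widest HP1c and HP1b peaks overlapped each other on 3LHet, a contig of pericentromeric sequence of arm 3L, at 1394683 to 1397718 and 1395637 to 1397761.

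The first question was whether the 4 factors occupy the same places. ROW and WOC shared most of their sites: 74.4% of ROW peaks (95% CI 73.3 to 75.6) overlapped a WOC peak and 81.5% of WOC peaks (80.3 to 82.5) overlapped a ROW peak. Circular shifts of the other list along each arm gave 4.61% and 5.03%, so the overlaps were 16.1 and 16.2 times chance. HP1b lay mostly inside the HP1c set, with 75.3% of HP1b peaks (73.6 to 77.0) overlapping HP1c, 14.4 times chance, while 44.3% of HP1c peaks (42.8 to 45.8) overlapped HP1b. The HP1 proteins also met ROW and WOC. Of HP1c peaks, 57.5% overlapped ROW and 62.2% overlapped WOC, and of HP1b peaks, 59.3% and 67.3% did. From the longer ROW and WOC lists, 45.5% of ROW peaks overlapped HP1c and 27.8% overlapped HP1b, against 53.5% and 34.3% of WOC peaks. All 12 ordered pairs exceeded every one of the 10000 shifts (one-sided permutation test, adjusted p = 1e-04, the smallest the shifts can give), with folds over chance from 10.6 to 16.2. The size of the fold depended on how overlap was defined and on the contigs used. It was 24.1 to 41.5 when centres had to lie within 200 bp and 5.98 to 9.03 when a gap of 500 bp was allowed. Over the main arms alone it was 14.97 to 28.4, and HP1c with HP1b (28.4) then exceeded ROW with WOC (20.5).

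H3K4me3 separated ROW and WOC from the HP1 proteins. Of ROW peaks, 46.5% (95% CI 45.2 to 47.9) overlapped an H3K4me3 peak, 8.04 times the 5.78% of shifted lists, and of WOC peaks 42.3% (40.9 to 43.7), 7.62 times chance. HP1c and HP1b overlapped the mark less often, with 16.4% of HP1c peaks (15.3 to 17.6) and 13.8% of HP1b peaks (12.5 to 15.2), or 3.09 and 2.59 times chance. The differences between the HP1 proteins and ROW or WOC were tested directly after seeing the data, with odds ratios from 0.184 to 0.268 (Fisher's exact test, two-sided, p at most 5.16e-147 adjusted over 7 tests between lists). All of the folds exceeded every shift (one-sided permutation test, adjusted p = 1e-04, the smallest the shifts can give). Seen from the mark, 45.4% of H3K4me3 peaks carried ROW, 38.4% WOC, 11.2% HP1c and 5.64% HP1b, and 51.3% carried none of the factors. The H3K4me3 list included 616 peaks on the unplaced contigs U and Uextra, where no factor list had a peak. Whether these contigs had been removed from the factor lists is not given in the sources used here, so H3K4me3 values over all contigs count peaks at which a factor may never have been called. Without them the shares were 50.5%, 42.6%, 12.5% and 6.27%, and 45.9% carried none of the factors. Requiring the overlap to span at least 0.5 of the shorter peak, or the factor's centre to lie inside the H3K4me3 peak, lowered the folds to between 2.01 and 4.65. With 0.5 of the shorter peak they were 4.65 for ROW, 3.50 for WOC, 2.02 for HP1c and 2.05 for HP1b. ROW and WOC stayed above the HP1 proteins, but by less.

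Within the 6170 H3K4me3 peaks every pair of factors met more often than independence would give. ROW and WOC were both present at 2226 peaks, ROW without WOC at 578 and WOC without ROW at 141, an odds ratio of 88.1 (95% CI 72.7 to 107). HP1c and HP1b were together at 289 peaks, HP1c without HP1b at 403 and HP1b without HP1c at 59, an odds ratio of 65.9 (48.9 to 88.7). Most HP1 peaks at the mark were also ROW and WOC sites. Of the 692 H3K4me3 peaks with HP1c, 636 also had ROW (odds ratio 17.3, 13.1 to 22.9) and 617 also had WOC (17.5, 13.7 to 22.4). Of the 348 with HP1b, 321 had ROW (16.0, 10.8 to 23.8) and 321 had WOC (21.9, 14.8 to 32.6). All 6 pairs passed Fisher's exact test (two-sided), the weakest at an adjusted p of 1.66e-81 for ROW with HP1b. Over the 5554 H3K4me3 peaks outside the unplaced contigs the odds ratios were 71.3 for ROW with WOC, 58.4 for HP1c with HP1b and 13.0 to 18.4 for the other pairs. With an overlap of 0.5 of the shorter peak they rose to between 25.6 and 199. Over H3K4me3 peaks above the median fold enrichment ROW with WOC fell to 58.2 and HP1c with HP1b to 39.5. WOC with HP1c (16.8) and WOC with HP1b (17.7) fell too, while ROW with HP1c rose to 23.2 and ROW with HP1b to 20.5.

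Merging the 4 factor lists gave 7897 regions, which fell into a few large classes. ROW with WOC and no HP1 protein was the most frequent, with 1713 regions, of which 66.9% (95% CI 64.6 to 69.1) carried H3K4me3. All 4 factors were present at 1235 regions (15.6%), of which 434 carried the mark and 801 did not. ROW, WOC and HP1c without HP1b were present at 877 regions, 54.8% of them marked (51.5 to 58.1). HP1c alone (1045 regions) and HP1b alone (412 regions) carried the mark at 4.02% (2.99 to 5.39) and 4.61% (2.97 to 7.09). ROW alone (1034 regions) was marked at 35.4% (32.5 to 38.4) and WOC alone (358 regions) at 21.2% (17.3 to 25.8). The count of 1235 was 95.5 times the mean of 12.9 in 1000 sets of shifted lists, whose maximum was 31 (one-sided permutation p = 0.001, the smallest they can give). Among the 2673 marked regions the 434 with all 4 factors were 2.83 times the 153 expected from independent factors. That expectation is raised because every region holds at least 1 factor. Counted over all H3K4me3 peaks in place of merged regions, including peaks with no factor, 274 carried all 4 factors against 6.80 expected, a ratio of 40.3. Without the unplaced contigs 9.33 were expected, a ratio of 29.4. Using only peaks above the median of each list left 474 regions with all 4 factors and 146 of them with the mark.

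Regions were ranked within each class by the -log10 q of their H3K4me3 peak. Among those with all 4 factors the first were on chromosome 4 at 818067 to 818647 (fold enrichment 2.497, -log10 q 357) and at 225229 to 228089 (10.86, 282). The region of YHet, sequence of the Y chromosome, at 66071 to 66486 came next (2.997, 243). By fold enrichment, 2 of these 3 lay below the median of 3.57 of all H3K4me3 peaks. The top regions with ROW, WOC and HP1c but not HP1b were on 2R at 616065 to 617238 (fold enrichment 9.18) and 558492 to 559755 (8.93) and on 3L at 23143171 to 23144173 (8.44). ROW stood alone at strongly marked sites on 3L at 19902420 to 19902682 (7.75), 3194109 to 3194367 (7.72) and 3471959 to 3472420 (7.59). WOC alone reached 7.31 on 3R at 5168338 to 5168619. HP1c alone reached 7.49 on 3L at 23093629 to 23093931, and HP1b alone 7.82 on 2R at 1195661 to 1195919. Genes at these positions were not analysed here.

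**Figure D1:**
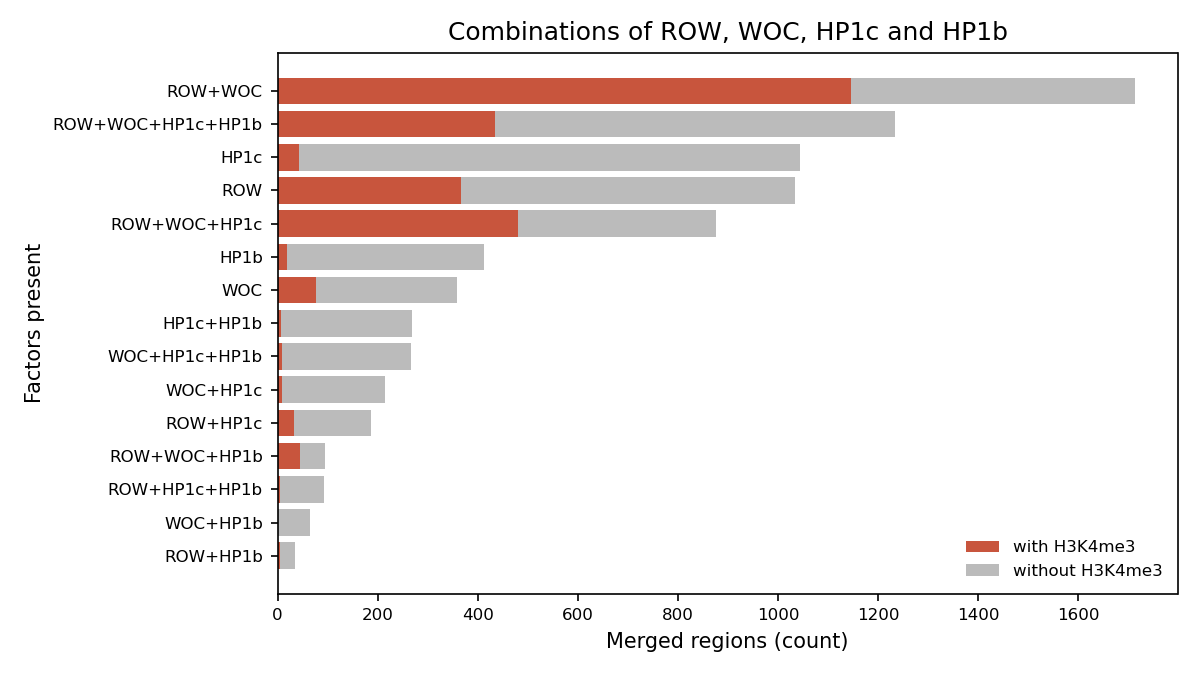
Number of merged regions (horizontal axis, count) for each combination of ROW, WOC, HP1c and HP1b (vertical axis), divided into regions with an H3K4me3 peak (red) and without (grey). ROW with WOC (1713 regions, 1146 marked) and all 4 factors (1235 regions, 434 marked) are the most frequent, and HP1c alone (1045 regions) has 42 marked regions.

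Sites shared by more factors were wider. Peak width was used because the factor lists give no value per peak. ROW peaks with no other factor had a median width of 316 bp (bootstrap 95% CI 311 to 324) and those with all 3 others 546 bp (528 to 570). The medians went from 289.5 to 559 bp for WOC, from 299 to 519 bp for HP1c and from 310 to 432.5 bp for HP1b. Nearly the same sites carried all 4 factors in every list, and they made up 49.9% of the 2508 HP1b peaks, 29.3% of HP1c, 25.5% of WOC and 23.4% of ROW, shares that follow the length of each list. Peaks with no other factor made up 7.31% of WOC, 16.4% of HP1b, 19.5% of ROW and 24.6% of HP1c. Across peaks, Spearman's rho between width and the number of other factors was 0.376 for ROW, 0.418 for WOC, 0.491 for HP1c and 0.373 for HP1b (two-sided permutation test, adjusted p = 1e-05 for each of the 4, the smallest it can give). Peaks are not independent replicates, and a wide peak meets another more easily by chance. With centres within 200 bp as the criterion, chosen after seeing the data, the 4 values of rho were between 0.271 and 0.376.

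HP1c and HP1b were scarce on X, which held 6.47% of HP1c peaks (95% CI 5.77 to 7.25) and 5.82% of HP1b peaks (4.97 to 6.81) against 14.7% of H3K4me3 peaks (odds ratios 0.401 and 0.359, Fisher's exact test, adjusted p = 1.6e-40 and 1.38e-33). On chromosome 4, a small chromosome rich in heterochromatin, lay 8.57% of HP1b, 6.68% of HP1c, 4.53% of WOC and 4.06% of ROW peaks, against 1.56% of H3K4me3 peaks (odds ratios 5.93, 4.53, 3.01 and 2.67). The heterochromatin contigs held 17.0% of HP1b, 14.3% of HP1c, 9.29% of WOC and 6.66% of ROW peaks, against 1.02% of H3K4me3 peaks (odds ratios 19.8, 16.2, 9.93 and 6.91). Adjusted p was at most 5.96e-16 for all 8 of these comparisons. Of 28 tests over 7 arms (Fisher's exact test, two-sided, adjusted over all 28), 12 were higher, 7 lower and 9 not called. Without the unplaced contigs, 8 were higher, all on chromosome 4 and the heterochromatin contigs. Another 12 were lower, on 2R, 3R and X for each factor, and 8 were not called. The arms are shares of a whole list, so the many factor peaks on chromosome 4 and the heterochromatin contigs lower every other share. A low share on 2R or 3R therefore does not show depletion there, and these arms were not tested over the main arms alone.

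For X, WOC passed the test against H3K4me3 and ROW did not, and both directions turned with only the peaks above the median of each list. X held 13.4% of ROW peaks (odds ratio 0.899, Fisher's exact test, adjusted p = 0.0648) and 12.6% of WOC peaks (0.838, adjusted p = 0.00298), and the odds ratios were 0.738 and 0.688 against the length of each arm and 0.793 and 0.740 without the unplaced contigs, all called. With only the peaks above the median of every list they were 1.44 and 1.47, because the share of H3K4me3 peaks on X fell from 14.7% to 8.91%. The median was that of width for the factors and of -log10 q for H3K4me3, so these are unlike measures. The share of factor peaks on X changed little, to 12.4% for ROW and 12.6% for WOC. The HP1c and HP1b odds ratios on X stayed below 1 there, at 0.655 and 0.632. Against the length of each arm in place of H3K4me3, the heterochromatin contigs gave odds ratios of 0.968 for ROW (exact binomial test, adjusted p = 0.685), 1.39 for WOC, 2.27 for HP1c and 2.78 for HP1b. Compared directly over the main arms, X held 8.19% of HP1c and 15.02% of ROW peaks (odds ratio 0.505, 95% CI 0.436 to 0.585, Fisher's exact test, adjusted p = 7.23e-20) and 7.82% of HP1b peaks (0.480 against ROW, 0.398 to 0.579, adjusted p = 1.41e-15). WOC and ROW did not pass the exact test (0.971, 0.864 to 1.09, adjusted p = 0.806), and neither did HP1b and HP1c (0.951, 0.772 to 1.17, adjusted p = 0.806). These direct comparisons were chosen after seeing the data and were adjusted over 18 tests.

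**Figure D2:**
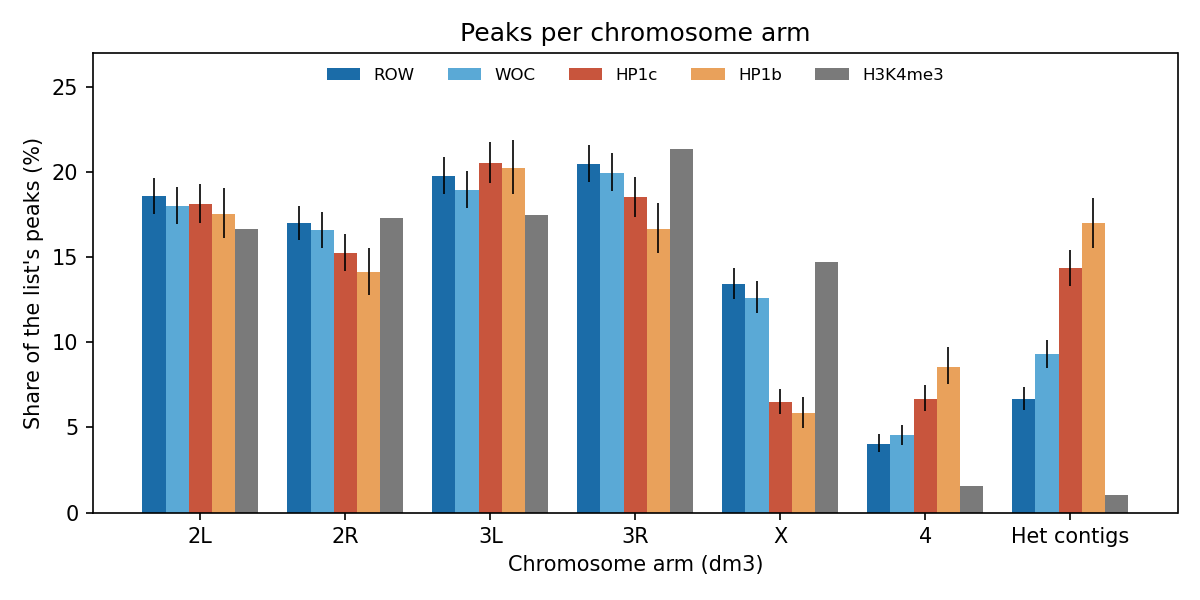
Share of each list's peaks (vertical axis, %) on each chromosome arm of dm3 (horizontal axis), with the heterochromatin contigs combined; error bars on the factor bars are 95% Wilson intervals, and the grey H3K4me3 bar is the background without an interval. HP1c (6.47%) and HP1b (5.82%) are low on X against H3K4me3 (14.7%), and all 4 factors exceed the mark on chromosome 4 and the heterochromatin contigs.

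ROW and WOC peaks lay close to H3K4me3 summits but beside them. The median distance from the peak centre to the nearest summit was 725 bp for ROW (bootstrap 95% CI 672 to 786), 914 bp for WOC (810 to 1032), 6709 bp for HP1c (6093 to 7395) and 7893 bp for HP1b (7339 to 8779). The distances differed between all 6 pairs (two-sided permutation tests over peaks), with adjusted p = 0.00048 for ROW against WOC, 0.0191 for HP1c against HP1b and 0.00015 for the others, for which the unadjusted p was the smallest the test can give. Within 1 kb of a summit lay 55.0% of ROW, 51.0% of WOC, 28.1% of HP1c and 22.7% of HP1b peaks. The medians of these nearby peaks were 373, 380, 429 and 453.5 bp. Centres under 200 bp from a summit made up 7.20% of nearby ROW peaks (95% CI 6.32 to 8.20), 4.89% of WOC, 7.21% of HP1c and 11.8% of HP1b. Those from 200 to 600 bp made up 76.9% (75.3 to 78.4), 80.0%, 71.5% and 58.6%. A factor's centre lay inside an H3K4me3 peak for 16.1% of ROW, 12.4% of WOC, 7.03% of HP1c and 7.18% of HP1b peaks. Over all peaks the medians rose to 3734, 4760, 13222 and 15500 bp when only H3K4me3 peaks above the median were kept, and to 2516 bp for ROW and 3029.5 bp for WOC with only the factor peaks narrower than the median.

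**Figure D3:**
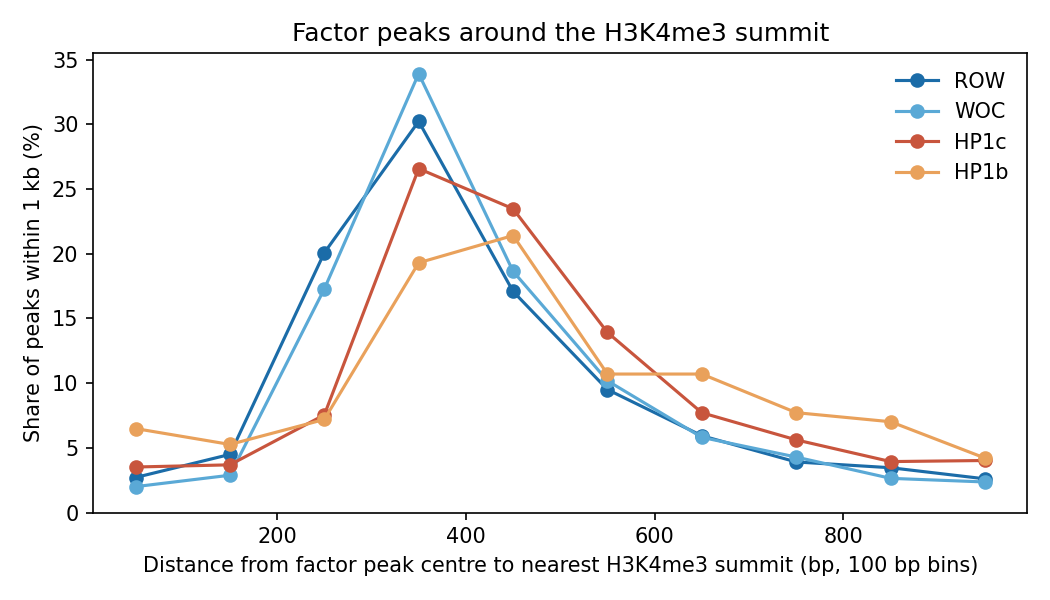
Share of factor peaks within 1 kb of an H3K4me3 summit (vertical axis, %) by distance from the peak centre to that summit (horizontal axis, bins of 100 bp), 1 line per factor. ROW (30.2%), WOC (33.9%) and HP1c (26.6%) are highest at 300 to 400 bp and HP1b (21.4%) at 400 to 500 bp.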

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

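On 3 contigs either H3K4me3 or the factors had peaks and the other did not. The H3K4me3 list had 616 peaks on the unplaced contigs U and Uextra (69 and 547), 9.98% of the list, with a median fold enrichment of 2.02 and no ROW, WOC, HP1c or HP1b peak on either contig. The 3 peaks with the highest -log10 q of the whole H3K4me3 list (1058, 895 and 846) lay there, with fold enrichments of 3.45, 3.49 and 3.76. Each factor list had 1 peak over nearly the whole mitochondrial genome, 19451 bp long for ROW, 19447 bp for WOC, 19469 bp for HP1c and 19434 bp for HP1b, where the H3K4me3 list had none.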

How the results depend on the processing

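No paired analysis was possible because each antibody has 1 list with its replicates combined and no column carries a replicate number; leaving out a replicate was impossible for the same reason. Promoter, gene list, head-to-head gene and motif alternatives were not run, for want of a matching annotation, and width in place of the authors' value was already the measure. All 72 alternatives for factor pairs (folds of 5.98 to 41.5), 24 for H3K4me3 overlap (2.01 to 11.6), 30 for co-occupancy (odds ratios of 13.0 to 199), 8 for width and sharing (rho of 0.271 to 0.496) and 4 for proximal shares (1.31 to 2.70, chosen after seeing the data) kept their direction and their side of the threshold. Of 84 for arms, 52 did, 9 lost the call, 8 gained it and 15 changed direction. In 9 of the 15 neither value was called. Against arm length these were ROW on 2R (1.05), WOC on 2R (1.02), WOC on 3L (0.997) and HP1b on 2L (0.982). Without the unplaced contigs they were WOC on 2L (0.969), WOC on 3L (0.972), HP1c on 2L (0.976) and HP1b on 2L (0.938). In both settings only the background changed: leaving out the unplaced contigs lowered the 2L odds ratio of every factor 1.136-fold. With peaks above the median of each list WOC on 3L turned (0.906), and the cause was not tested. On X, ROW reached 0.738 against arm length and 0.793 without the unplaced contigs (chosen after seeing the data), both now called. With peaks above the median of each list, ROW on X (1.44) and WOC on X (1.47) changed direction, because that choice also lowered the share of H3K4me3 peaks on X from 14.7% to 8.91%; ROW, HP1c and HP1b on 3L turned to 0.925, 0.949 and 0.921, and the cause was not tested. ROW on the heterochromatin contigs turned from 6.91 to 0.968 against arm length, since few H3K4me3 peaks lie there. For the combinations 4 of 7 alternatives stayed close to the main value. Regions with all 4 factors fell to 474 and those with the mark to 146 with peaks above the median of each list, which leaves fewer peaks. The ratio to independence rose from 2.83 to 40.3 over all H3K4me3 peaks (chosen after seeing the data), which include peaks with no factor. There H3K4me3 peaks were counted in place of merged regions, and without the unplaced contigs the ratio was 29.4. Of 24 alternative distances 9 stayed within the main interval. Measured to the centre of the mark, the median distance was 820 bp for all ROW peaks and, within 1 kb, 434 bp for ROW, 448 bp for WOC, 513 bp for HP1c and 509 bp for HP1b. With H3K4me3 peaks above the median, which leaves fewer summits, the medians were 3734, 4760, 13222 and 15500 bp. With factor peaks narrower than the median (chosen after seeing the data) they were 2516 bp for ROW and 3029.5 bp for WOC, and within 1 kb 327, 329.5, 396 and 429 bp for ROW, WOC, HP1c and HP1b; the cause was not tested. Unknown depth limits every statement that a peak is missing from a list.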

Other observations

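H3K4me3 peaks that carried both ROW and WOC were stronger than those with no factor; peaks with other combinations were not tested. Outside the unplaced contigs, H3K4me3 peaks with no factor had a median fold enrichment of 3.18 (bootstrap 95% CI 3.13 to 3.23, 2550 peaks). Those with ROW and WOC but no HP1 protein had 4.08 (4.03 to 4.13, 1580 peaks), those with HP1c as well 4.59 (4.39 to 4.75, 331 peaks) and those with all 4 factors 4.75 (4.37 to 5.05, 274 peaks). Each of these 3 classes differed from peaks with no factor (two-sided permutation test over peaks, unadjusted p = 1e-04, the smallest it can give, for each). The median H3K4me3 peak width went from 580.5 bp with no factor to 898.5 bp with all 4 factors. A wide H3K4me3 peak meets a factor peak more easily by chance, so the classes differ partly by construction. The fold enrichments were not compared at like width. At regions with both ROW and WOC, the HP1 proteins were less frequent where the mark was present: HP1c was at 43.5% of 2105 marked regions and 66.0% of 1815 unmarked regions (odds ratio 0.397, 95% CI 0.349 to 0.452, Fisher's exact p = 2.34e-45), and HP1b at 22.7% and 46.9% (0.332, 0.289 to 0.381, p = 8.45e-58). Over the main arms without their proximal 2 Mb the odds ratios were 0.471 for HP1c (0.406 to 0.545) and 0.383 for HP1b (0.324 to 0.452).

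HP1b and HP1c in particular were frequent near the centromeres. The proximal 2 Mb of the main arms held 19.9% of main-arm HP1b peaks (95% CI 18.1 to 21.8), 15.9% of HP1c, 12.8% of WOC and 10.8% of ROW, against 6.34% of H3K4me3 peaks (odds ratios 3.67, 2.80, 2.16 and 1.78, Fisher's exact p at most 1.55e-15). H3K4me3 was itself low there: these 2 Mb make up 8.40% of the length of the main arms, against which HP1b was 2.37-fold, HP1c 1.90-fold, WOC 1.52-fold and ROW 1.28-fold higher and H3K4me3 0.754 times as frequent (exact binomial test, adjusted p at most 1.98e-08). On chromosome 4, all 4 factors were present at 126 of 317 regions (39.7%, 34.5 to 45.2), against 908 of 6793 regions (13.4%) on the main arms (odds ratio 4.28, 3.38 to 5.41, Fisher's exact p = 1.23e-29). Factor peaks were crowded on chromosome 4, with odds ratios against arm length from 4.10 for ROW to 9.10 for HP1b. Crowded peaks overlap more easily by chance, and the ratio of 4.28 was not set against such an expectation. At the distal end of 3R, from 27898572 to 27904900, 7 regions followed one another with centres 911 to 1029 bp apart, 5 of them with all 4 factors and 4 with H3K4me3. The sequence of the build was not used, so copies of a repeated sequence could not be told apart from 7 separate sites. The comparisons near the centromeres, on chromosome 4 and at the end of 3R were chosen after the data had been seen.

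In the 3 patterns that follow, the tests on proximal and heterochromatic sequence, on high-copy sequence and on random summits were chosen only after the result was seen, and no biological explanation was tested. HP1c peaks were scarce on X, also among H3K4me3 peaks with ROW and WOC, where HP1c was at 7.63% of 262 peaks on X and 26.6% of 1848 on the other main arms (odds ratio 0.228, 95% CI 0.143 to 0.365). A lower dose of X in male heads may take weak peaks below the calling threshold, and was predicted to leave the widest peaks alike. Among peaks wider than the median of each list the odds ratio of HP1c against ROW on X was 0.556 (0.448 to 0.689). The ratio shows only that the scarcity held among wide peaks. It cannot exclude a dose effect, because a lower dose could also narrow peaks on X and take them out of the widest. H3K4me3 itself did lose share on X among its stronger peaks (14.7% to 8.91%), so a dose effect on that list is not excluded. Crowding of HP1c in pericentromeric sequence would vanish without the proximal 2 Mb of the arms, where the ratio was 0.520 (0.446 to 0.606). Whether the scarcity on X of HP1c relative to ROW reflects binding was not tested. Width stood in for peak strength, and the sex of the flies is not given in the labels used here.

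The 801 regions with all 4 factors and no H3K4me3 are a second pattern. A mark that lies beside the region was found for few of them, since 8.61% (95% CI 6.86 to 10.8) had an H3K4me3 peak within 500 bp. High-copy sequence called with any antibody remains open, since heterochromatin contigs, chromosome 4, the mitochondrial genome and the proximal 2 Mb of the arms held 47.9% of these regions (44.5 to 51.4) and 15.6% of the sequence length, so an artefact of copy number may account for part of them. The excess over length is not particular to these regions. Of all HP1b peaks 17.0% lay on heterochromatin contigs and 8.57% on chromosome 4, and 19.9% of its main-arm peaks were proximal. For ROW these shares were lower, at 6.66%, 4.06% and 10.8%. The mitochondrial genome, present in many copies, is itself among these regions, with a peak in all 4 factor lists and none in the H3K4me3 list. The regions were chosen for lacking the mark, so its absence there cannot count against an artefact of copy number. Without the sequence of the build or the IgG signal, neither used here, such an artefact cannot be told apart from true binding.

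Factor centres lay beside the H3K4me3 summit. If wide or merged peaks had displaced centres, narrow peaks might sit on the summit, but among ROW peaks narrower than the median and within 1 kb 10.3% (95% CI 8.62 to 12.3) lay under 200 bp from it, against 7.20% of all ROW peaks. A summit placed at random in a broad mark could leave few factor centres near it too, but moving each summit to a random base of its own H3K4me3 peak put 16.4% of ROW peaks under 200 bp (95% range 15.2 to 17.6 over 1000 draws). The observed median within 1 kb, 373 bp, was nonetheless shorter than the 433 bp of random summits, so observed distances gathered at intermediate values.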
